A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

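Gene expression was measured on 6 Affymetrix yeast arrays, each from 1 culture of the xylose-engineered strain YSX3 or its respiration-deficient derivative. The deposited values are linear intensity per probe set, per the labels; the software, averaging and scaling behind them are not given in the sources used here. Of 9335 probe sets, 1 had no value and 60 were controls, which left 9274 yeast probe sets. Of these, 6504 mapped to 1 gene symbol, 328 to several and 2442 to none, so that 5656 genes were measured, 315 of them by several probe sets.

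Each array was scaled to a common median, values below the 25th percentile (61.7) were set to that floor, and log2 was taken. The probe set with the highest mean stood for its gene. A gene entered the fit if at least 1 array lay above the floor, which held for 5462 genes. Differences between 2 arrays were left out where both lay at the floor and are bounds where 1 did.

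Samples were grouped by sugar (glucose, xylose) and by background (aerobic, oxygen-limited, petite). A linear model with background and sugar was fitted per gene with limma 3.58.1 in R 4.3.3, with 2 residual degrees of freedom, moderated variances and Benjamini-Hochberg adjustment at 0.05. It gave 3 comparisons: xylose minus glucose, oxygen-limited minus aerobic, and petite minus aerobic. With 1 array per condition the model assumes that sugar acts alike in each background, and no interaction was tested. The 7 differences between single arrays are description without a p-value. The oxygen and petite comparisons share the aerobic arrays, so they were not set against each other.

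A set of 33 gene lists was fixed before the data were examined, as were the processing, the tests and most alternatives. The strain marker list had 2 measured members, under the minimum of 3, and was not tested. For each list the median, the counts of members that passed over all genes and when adjusted over the list alone, limma camera with a preset correlation of 0.01 and with an estimated correlation, and limma fry were computed. List medians of single pairs were placed among 10000 random lists of like intensity. Such lists hold unrelated genes, so the placement does not allow for members that move together.

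Genes were named by a rule also fixed beforehand. It took the 12 highest and 12 lowest genes per comparison among those that passed with 1 sign in every pair, filled with genes that missed the threshold where fewer passed. It added the 5 highest and 5 lowest per pair among brighter genes, 2 to 4 members of each described list with those going against it at least 2-fold, and a set of genes of xylose, hexose, ethanol, glycerol and respiratory metabolism. Members named because they made up a small count, such as GLG1, ATH1 and GLC3, were chosen after values were seen. Transposon, dubious and unnamed genes were counted but not named.

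Alternatives were the values as deposited, quantile normalization, floors at the 10th and 40th percentile, the mean over a gene's probe sets, a 3-fold threshold, a variance trend in limma, and leaving out each pair in turn. After the data were seen, alternatives were added that removed a running median along the probe set numbers (window 201) from each array or left out the high-numbered probe sets, which held 712 of the 5462 genes in the fit. The pipeline was tested on simulated data. For the sugar comparison it recovered 22.3% of 2-fold and 71.7% of 4-fold changes, and for the oxygen comparison 2.33% and 54.0%, with 1.40% and 1.16% of calls false. The simulated arrays had independent noise and, apart from the changed genes, no differences between backgrounds, array sets or probe set numbers. Changed genes were drawn from those well above the floor. These rates therefore need not hold for the real arrays. The number of arrays limits the precision. Measurements of the Pichia genes by other methods were not used here.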

Results

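Messenger RNA of a budding yeast strain engineered to use xylose, a pentose from plant biomass, was measured on 6 Affymetrix yeast arrays. The strain YSX3 carries the genes XYL1, XYL2 and XYL3 of the xylose-fermenting yeast Pichia stipitis, which encode xylose reductase, xylitol dehydrogenase and xylulokinase. Each of 3 backgrounds was sampled once on glucose and once on xylose: aerobic culture, oxygen-limited culture, and a respiration-deficient (petite) mutant derived from the strain. Aerobic cultures held 20 g/L sugar and were harvested at an OD600 of 1, whereas oxygen-limited cultures held 40 g/L and were harvested at an OD600 of 30. The petite xylose sample was glucose-grown and then kept 24 hours in xylose medium. No condition had a replicate array, and the number of arrays limits the precision of every value. Median deposited intensity on the log2 scale lay 0.05 above the aerobic glucose array on the aerobic xylose array, 0.38 above it on both oxygen-limited arrays and 0.31 above it on both petite arrays, and values below were scaled to a common median. Between 88.0% and 90.5% of the 5656 measured genes lay above the intensity floor of 61.7 on each array. The Pichia genes have no probe set on this array.

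The first comparison asks how the yeast's own genes differ between xylose and glucose across the 3 backgrounds. On xylose, the high-affinity hexose transporter genes and the hexokinase gene HXK1 rose, and an alpha-factor gene fell. Lists of respiration, the tricarboxylic acid (TCA) cycle, gluconeogenesis, fatty acid oxidation, reserve carbohydrates and stress protection had positive medians, and those of ribosomes, ribosome biogenesis and ergosterol negative ones. At most 2 members of any of these lists passed over all genes. Limma camera called lists with a preset correlation of 0.01, but none with an estimated correlation, where the smallest was adjusted p = 0.674. With 2 residual degrees of freedom that second form could hardly call any list, so it leaves the shifts undecided. The preset lay below the estimated correlation of every list it called, so its adjusted p may be too small. Over the 3 backgrounds limma called 37 genes higher and 4 lower among 5462 tested, at an adjusted p under 0.05. The unadjusted counts at a p under 0.05 were 658 higher and 535 lower. With the floor at the 40th percentile limma called 0 in either direction (unadjusted 552 and 419), and also 0 without the oxygen-limited pair (unadjusted 324 and 197). Without the petite pair it called 12 higher, of which 6 were among the 37, and 0 lower (unadjusted 505 and 253). Without the aerobic pair it called 42 higher and 7 lower, of which 19 were among the 37 and 2 among the 4.

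Genes of sugar entry and sugar sensing were among those that rose most on xylose. The intensity of HXK1, the hexokinase that glucose represses, went from 333 to 2467 in aerobic culture, from 516 to 3868 under oxygen limitation and from 525 to 3386 in the petite mutant. Its difference was 2.83 on the log2 scale (limma adjusted p = 0.0113, higher in 3 of 3 pairs). The high-affinity transporter genes HXT6 and HXT7 rose by 3.27 and 3.14, each with a limma adjusted p of 0.0113 and higher in 3 of 3 pairs. These transporter genes are near-identical copies, so their probe sets need not tell them apart. MTH1, a repressor of transporter genes that acts when glucose is absent, rose by 3.18 (limma adjusted p = 0.0239, higher in 3 of 3 pairs). Conversely, HXT1 went from 1892 to 75 in aerobic culture, from 590 to the floor under oxygen limitation and from 835 to 246 in the petite mutant. Its mean difference of -3.23 and that of HXT3, -1.70, missed the threshold with limma adjusted p of 0.0829 and 0.085, although both were lower in 3 of 3 pairs. Among 12 measured hexose transport genes with a median of 0.21, 2 rose and 0 fell, and 5 rose and 2 fell when adjusted over the list alone.

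The other genes with the largest increases were of varied function. TMA10, a stress-induced protein that associates with ribosomes, had the highest estimate, 3.65. FAT3 takes part in fatty acid uptake, ATO2 encodes an acetate and ammonium transporter and MPC3 a subunit of the mitochondrial pyruvate carrier. Their estimates were 3.24, 3.11 and 2.84. DDR2, a general stress gene, rose by 3.11. IGD1, an inhibitor of glycogen debranching, rose by 2.78, FMP45, a cell-cortex and mitochondrial protein, by 2.65, and MSC1, a poorly characterised mitochondrial protein, by 2.48. Among these 8 genes the limma adjusted p ran from 0.0113 for TMA10 to 0.0481 for MSC1, and each was higher in 3 of 3 pairs. TMA10, FAT3, ATO2, IGD1 and MTH1 had glucose values at the floor, so their fitted values, like those of any gene with an array there, depend on it. FAT3 has a probe set at the high end of the probe set numbers, a stretch with 712 of the 5462 genes where the oxygen-limited arrays were dimmer. Under oxygen limitation this stretch was also higher on xylose, with a median of 0.24 against -0.09 for lower numbers. RGI1, a gene of respiratory energy metabolism, also rose by 2.43 (limma adjusted p = 0.0113, higher in 3 of 3 pairs).

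**Figure D1:**
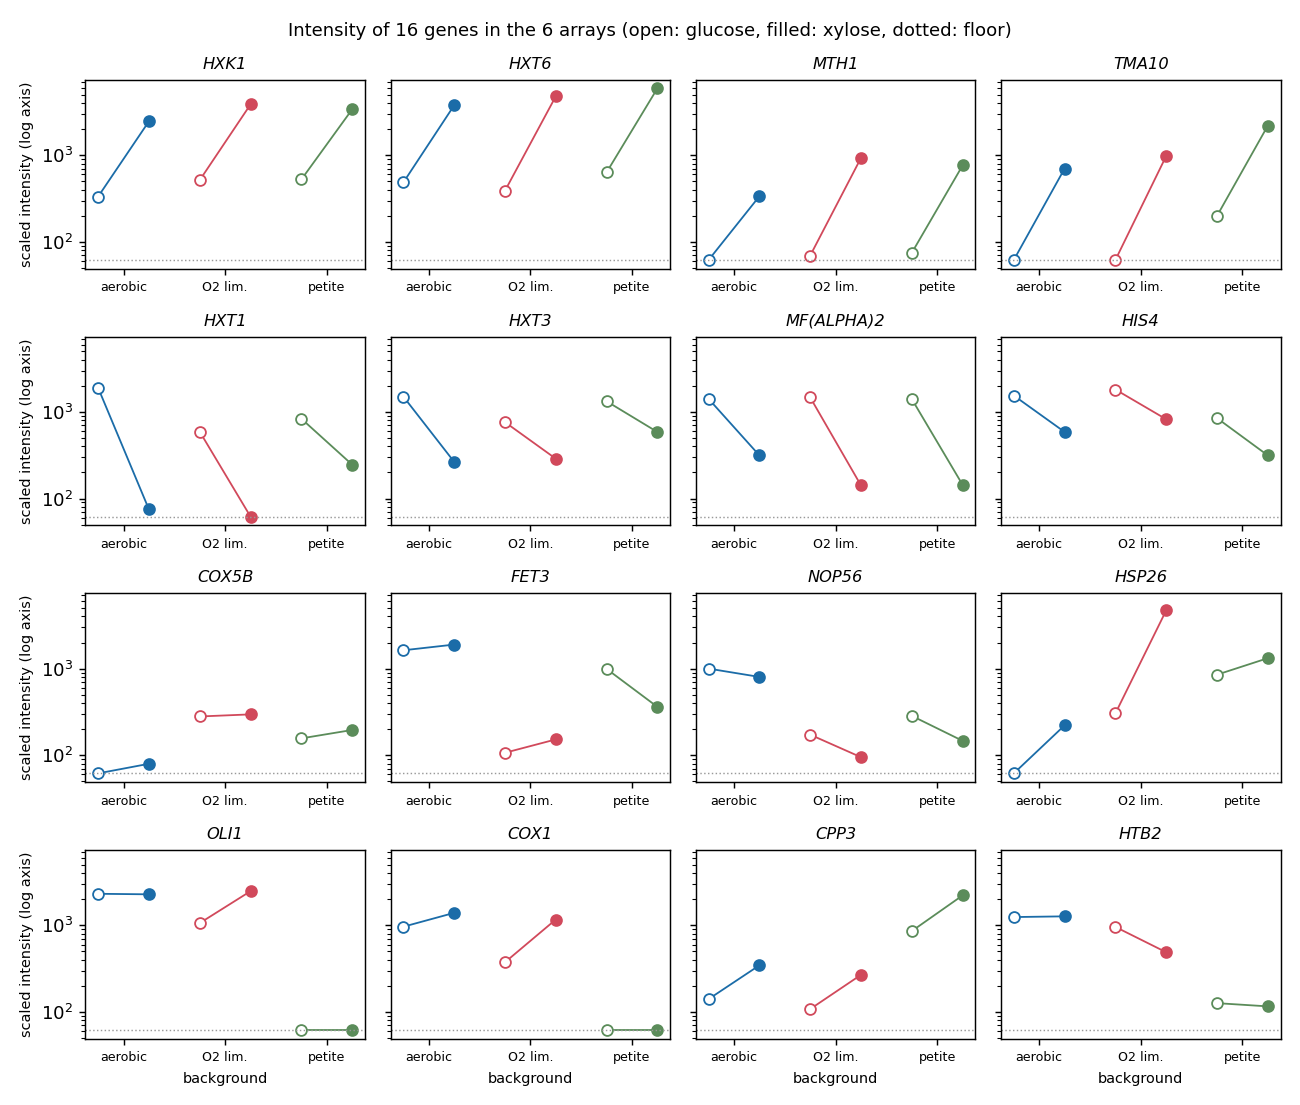
Scaled intensity of 16 genes on the 6 arrays, on a log axis, with 1 open point for glucose and 1 filled point for xylose in each background; a dotted line marks the floor of 61.7. HXK1 was higher on xylose in each background, 333 against 2467 in aerobic culture, whereas FET3 differed mainly between oxygen supplies and OLI1 lay at the floor in both petite samples.

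Only 4 genes fell on xylose. MF(ALPHA)2, a gene for the alpha-factor mating pheromone, went from 1415 to 315 in aerobic culture, from 1472 to 142 under oxygen limitation and from 1408 to 144 in the petite mutant. Its estimate was -2.95 (limma adjusted p = 0.0318, lower in 3 of 3 pairs). ARI1, an aldehyde reductase, fell by 2.06, the histidine biosynthesis gene HIS4 by 1.32 and the leucyl-tRNA synthetase gene CDC60 by 1.22, with limma adjusted p of 0.0156, 0.043 and 0.043 and lower values in 3 of 3 pairs for each. The next lowest genes with 1 sign in every pair missed the threshold. They were the thiamine-repressed phosphatase PHO3 at -2.08, the enolase ENO2 at -1.86, the chaperone SSA2 at -1.86, the polyamine exporter TPO2 at -1.72, the lactate dehydrogenase DLD3 at -1.68 and the histidine gene HIS1 at -1.55, besides HXT1 and HXT3.

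Respiratory genes shared the direction but few passed singly. The 22 nuclear genes of the respiratory chain had a median difference of 0.97; 0 rose and 0 fell under limma over all genes, and 18 rose when adjusted over the list alone. The internal NADH dehydrogenase NDI1 had the largest estimate, going from 525 to 1221, 295 to 1673 and 212 to 368 in the 3 backgrounds, followed by the cytochrome subunits QCR10 at 1.27 and COX5A at 1.23. Of 16 TCA cycle genes with a median of 0.73, 2 rose, 0 fell and 14 did not pass, with 6 rising when adjusted over the list alone. The 2 were the succinate dehydrogenase subunits SDH2, at 1.91 (limma adjusted p = 0.0481, higher in 3 of 3 pairs), and SDH4, at 1.73 (limma adjusted p = 0.043, higher in 3 of 3 pairs). The 14 ATP synthase genes had a median of 0.72, with 0 rising and 7 rising when adjusted over the list alone. For 67 mitochondrial ribosomal protein genes the median was 0.33 and 0 rose, also when adjusted over the list alone.

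Lists for growth on poor carbon sources had positive medians too. Of 9 glyoxylate and gluconeogenesis genes with a median of 1.34, 1 rose, the cytosolic malate dehydrogenase MDH2 at 1.34 (limma adjusted p = 0.043, higher in 3 of 3 pairs), and 5 rose when adjusted over the list alone. The isocitrate dehydrogenase IDP2 was at 2.22, PCK1 at 1.80, FBP1 at 1.34 and the isocitrate lyase ICL1 at 1.01; these 4 missed the threshold over all genes, with limma adjusted p from 0.0526 to 0.21 and higher values in 3 of 3 pairs. Of 14 glucose-repressed regulators and sugar genes with a median of 1.19, 2 rose and 10 rose against 2 falling when adjusted over the list alone. The 2 were MTH1 and ADR1, an activator of alcohol and fatty acid use, at 1.89 (limma adjusted p = 0.0286, higher in 3 of 3 pairs). HAP4, the activator of respiration genes, was at 2.07 with a high-numbered probe set, and the repressor MIG2 went against the list at -1.13. Among 19 genes of fatty acid oxidation with a median of 0.56, 1 rose, the thiolase POT1 at 1.90 (limma adjusted p = 0.0415, higher in 3 of 3 pairs), and 4 rose when adjusted over the list alone.

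Reserve carbohydrate and stress lists also had positive medians on xylose. The 17 trehalose and glycogen genes had a median of 0.88; the glycogen branching enzyme GLC3 rose by 1.95 (limma adjusted p = 0.043, higher in 3 of 3 pairs), and 11 rose and 1 fell when adjusted over the list alone. The glycogen phosphorylase GPH1 was at 1.88 and the phosphoglucomutase PGM2 at 1.71. Among 22 heat shock and general stress genes with a median of 0.62, DDR2 alone rose, 5 rose when adjusted over the list alone, and SSA2 went against the list at -1.86. HSP12, a membrane stress protein, was at 3.25 and missed the threshold (limma adjusted p = 0.0526, higher in 3 of 3 pairs). The 18 oxidative stress genes had a median of 0.62, with 0 rising over all genes and 9 when adjusted over the list alone, led by the peroxidases GPX1 at 1.86 and PRX1 at 1.59. The probe sets of GPX1 and PCK1 are high-numbered.

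Lists of central sugar metabolism had medians close to 0 over the 3 backgrounds. The median of 16 glycolysis genes was -0.14, with -0.10, 0.23 and -0.63 in the aerobic, oxygen-limited and petite pairs. Their mean was 0.01, and limma camera put the list lower (adjusted p = 0.85). HXK1 alone rose; 2 rose and 1 fell when adjusted over the list alone, among them the glucokinase GLK1 at 0.81 and ENO2. HXK2, the hexokinase used on glucose, was at -0.57. The 17 ethanol and acetate genes had a median of -0.06 and a mean of 0.38, with camera pointing up (adjusted p = 0.85); 1 rose, the mitochondrial aldehyde dehydrogenase ALD4 at 2.31 (limma adjusted p = 0.0442, higher in 3 of 3 pairs), and 4 rose and 2 fell when adjusted over the list alone. ADH1 was at -0.31 and PDC1 at -0.23, both short of the threshold. ADH2, the ethanol-oxidising alcohol dehydrogenase, went from 143 to 1621 in aerobic culture but from 177 to 139 under oxygen limitation and from 1350 to 1056 in the petite mutant. For 11 pentose phosphate genes the median was -0.10 and the mean 0.20, with camera pointing up (adjusted p = 0.88) and 4 rising and 2 falling when adjusted over the list alone. The minor transketolase TKL2 was at 2.11 and the transaldolase paralog NQM1 at 1.90, whereas the ribose-5-phosphate isomerase RKI1 was at -1.03.

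Of the yeast's own xylose genes 1 passed. GRE3, an aldose reductase that accepts xylose, was at 0.01, the endogenous XYL2 at 0.14 and the xylulokinase XKS1 at 0.26, all short of the threshold and with pairs of either sign. In aerobic, oxygen-limited and petite cells GRE3 was at 0.26, 0.27 and -0.48, XYL2 at 0.25, 0.51 and -0.34, XKS1 at 0.66, 0.62 and -0.50, and the list median at 0.42, 0.57 and -0.40. Among the 6 measured genes of this list, with a median of 0.20, GCY1, an aldo-keto reductase, alone rose, by 2.01 (limma adjusted p = 0.0415, higher in 3 of 3 pairs), with 2 rising and 1 falling when adjusted over the list alone. SOR1 has no probe set of its own. The integration markers LEU2 and URA3 were at -0.32 and 0.00. A control probe set of URA3 differed, going from 3190 on glucose to 1196 on xylose in aerobic culture. It went from 2923 to 3192 under oxygen limitation and from 2638 to 2095 in the petite mutant. For the 10 glycerol genes the median was -0.01 and the mean 0.24; the mitochondrial glycerol-3-phosphate dehydrogenase GUT2 rose by 2.25 (limma adjusted p = 0.0337, higher in 3 of 3 pairs), and GPD1 was at 0.28.

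Growth-related lists had negative medians on xylose, with few single members passing. Medians were -0.30 for 80 cytosolic ribosomal protein genes, -0.41 for 27 ribosome biogenesis genes and -0.58 for 22 ergosterol genes, with 0 rising and 0 falling in each under limma, also when adjusted over the list alone. Their lowest members were RPS9B at -0.95, the RNA helicase DBP2 at -1.20 and the sterol dehydrogenase ERG26 at -1.02. Of 40 amino acid biosynthesis genes, 1 fell, HIS4, also when adjusted over the list alone, and 0 rose in either count. The lysine genes LYS9 at 1.79 and LYS20 at 1.43 went against the list without passing. Of 4 alpha-specific genes MF(ALPHA)2 fell, 2 fell when adjusted over the list alone, and the median was -1.25; MF(ALPHA)1 was at -1.40 and the pheromone receptor STE3 at -0.16.

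Limma camera with a preset correlation of 0.01 placed 15 of 32 lists away from the other genes on xylose. The adjusted p was 3.8e-11 for the respiratory chain, 3.8e-09 for the mitochondrial ribosome, 6.5e-08 for cytosolic ribosomal proteins, 2.2e-06 for trehalose and glycogen, 2.1e-06 for ribosome biogenesis, 9.1e-06 for ATP synthase and 4.4e-05 for ergosterol. It was 9.4e-05 for the TCA cycle, 1.9e-05 for glyoxylate and gluconeogenesis, 1.3e-05 for both fatty acid oxidation and oxidative stress, 2.1e-04 for glucose-repressed genes, 4.3e-04 for heat shock, 0.00614 for alpha-specific genes and 0.0373 for amino acid biosynthesis. None of these held in camera with an estimated correlation, where the smallest was adjusted p = 0.674, for the mitochondrial ribosome among others. That form rests on 2 residual degrees of freedom and could hardly call any list, so it cannot tell whether a list shifted. The preset form is not secure either. Estimated correlations lay above the preset 0.01 for every list it called, from 0.02 for fatty acid oxidation to 0.90 for ATP synthase. They were 0.82 for the respiratory chain and 0.40 for cytosolic ribosomal proteins. Where such correlations hold, the adjusted p of the preset form are too small. The estimates themselves rest on few degrees of freedom. In limma fry the smallest adjusted p for a shift in 1 direction was 0.159. For changes in either direction it was 0.00188, for glycolysis, which camera did not call. The respiratory chain, ATP synthase, oxidative stress, cytosolic ribosomal proteins and ergosterol missed 0.05 in that form of fry. Their adjusted p were 0.0939, 0.168, 0.0603, 0.114 and 0.192, while the other lists that camera called passed. Lists that camera did not call on xylose included the galactose regulon at a median of 0.03, hypoxic genes at -0.12, the retrograde response at 0.08, drug resistance at 0.11, thiamine at 0.02, histones at -0.06, a-specific genes at -0.04, meiosis at -0.08 and the mitochondrial genome at 0.37. The iron regulon had a median of -0.08 while camera pointed up (adjusted p = 0.88), and the phosphate regulon a median of 0.05, -0.03 with the probe set number trend removed, while camera pointed down (adjusted p = 0.985).

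**Figure D2:**
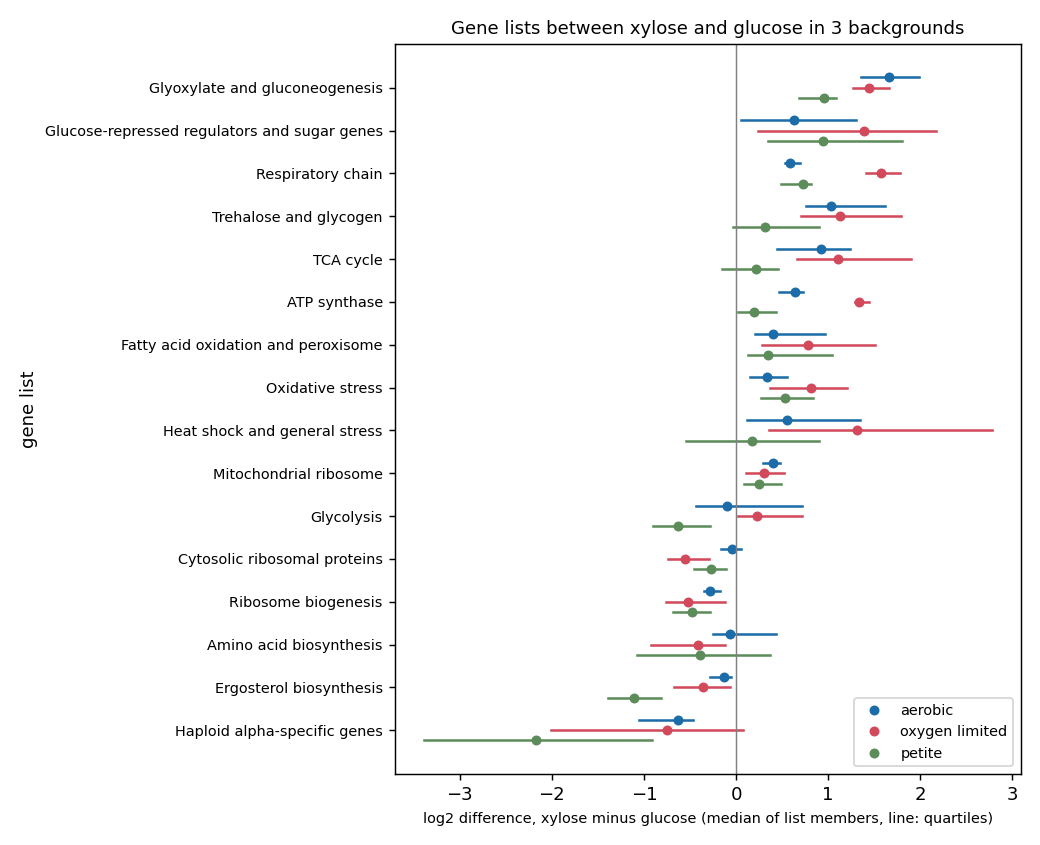
Median log2 difference, xylose minus glucose, of 16 gene lists in aerobic, oxygen-limited and petite cells, with lines from the lower to the upper quartile of the members. The respiratory chain was higher on xylose in each background, at 0.59, 1.58 and 0.73, whereas cytosolic ribosomal proteins in aerobic culture lay at -0.04, which turned to 0.0077 without scaling.

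Differences between the single pairs were not tested, and the spread between probe sets of the same gene was 0.17 in the aerobic pair, 0.40 in the oxygen-limited pair and 0.31 in the petite pair. This spread is between probe sets on the same 2 arrays and does not measure variation between arrays or cultures. In aerobic culture 161 genes were at least 2-fold higher and 108 lower on xylose, of 5138 compared. Under oxygen limitation the counts were 457 higher and 221 lower of 5217, and in the petite mutant 302 higher and 277 lower of 5246. In all 3 pairs 70 genes were at least 2-fold higher, against 0.777 if the pairs were independent, and 12 were lower, against 0.249. In the aerobic pair the lactate dehydrogenase CYB2 was higher by 4.24, HSP12 by 4.04, the alanyl-tRNA synthetase ALA1 by 3.89, the glyoxylate aminotransferase AGX1 by 3.56 and FAT3 by at least 3.54. The lowest there were HXT1 at -4.66, PHO3 at -2.52, HXT3 at -2.50, the ribosome biogenesis gene RLP7 at -2.30 and MF(ALPHA)2 at -2.17. Under oxygen limitation AGX1 led at 4.42, followed by the mitochondrial organisation gene NCA3 at 4.22 through a high-numbered probe set, the formate dehydrogenase FDH1 at 4.05 or more, TMA10 at 3.99 or more and the chaperone HSP26 at 3.95; MF(ALPHA)2 at -3.38, HXT1 at -3.26 or below, DLD3 at -3.19 or below, TPO2 at -2.95 or below and the phosphate regulator SPL2 at -2.79 were lowest. In the petite pair the stationary-phase gene SPG4 was higher by 4.16, FAT3 by 4.08, the phosphate transporter PHO84 by 3.77, the carbonic anhydrase NCE103 by 3.56 and the cell wall gene PIR3 by 3.56. MF(ALPHA)1 at -3.69, SSA2 at -3.45, MF(ALPHA)2 at -3.29, ENO2 at -2.54 and PHO3 at -2.49 were lowest there.

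Group medians of the single pairs were not tested against each other either. The respiratory chain was higher by 0.59 in aerobic culture, 1.58 under oxygen limitation and 0.73 in the petite mutant, each above 100% of 10000 random lists of like intensity. TCA cycle genes stood at 0.92 and 1.11 in the first 2 backgrounds and 0.22 in the petite mutant, where the citrate synthase CIT1 was higher by 1.66 and the aconitase ACO1 was at -1.98. Ergosterol genes were at -0.13, -0.36 and -1.11, and 0% of the random lists had a lower median in the petite pair. Random lists hold unrelated genes, whereas the estimated correlation was 0.82 for the respiratory chain and 0.49 for ergosterol genes. Lists whose members move together can lie outside random lists after any difference between 2 arrays. These shares are therefore description and no test of sugar. CIT2, the peroxisomal citrate synthase, was at -0.21, -2.10 and 1.00.

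The second comparison asks how cells under oxygen limitation differ from aerobic cells over both sugars; sugar concentration, cell density and culture volume differed along with the oxygen supply. The heat shock genes HSP30 and HSP26 rose under oxygen limitation, but of 22 heat shock genes 4 rose and 3 fell. Of 22 hypoxic and anaerobic genes 2 rose, the cytochrome genes COX5B and CYC7, and 2 fell, ANB1 and SML1. Of 27 ribosome biogenesis genes 24 fell, as did 34 of 80 cytosolic ribosomal protein genes, 9 of 18 iron regulon genes and 12 of 40 amino acid biosynthesis genes. Limma camera called lists with the preset correlation of 0.01, but none with an estimated correlation, where the smallest was adjusted p = 0.93. That second form could hardly call any list with 2 residual degrees of freedom, so it leaves the shifts undecided. Among all 5462 genes tested limma called 439 higher and 868 lower, so that 33.6% of the calls were higher. List counts are to be read against these totals. The 2 of 16 TCA cycle genes and 3 of 22 ergosterol genes that fell are no larger a share than among all genes. For hypoxic genes the share that rose was near that among all genes. With the values as deposited, where the oxygen-limited arrays lie 0.38 above the aerobic glucose array in their medians, the counts were 1032 higher and 430 lower, or 70.6% higher. With quantile normalization they were 432 and 558, or 43.6% higher.

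The heat shock proteins HSP30 and HSP26 had the largest estimates, 4.06 (limma adjusted p = 0.0251, higher in 2 of 2 pairs) and 3.36 (limma adjusted p = 0.0353, higher in 2 of 2 pairs). On xylose HSP30 went from 124 to 5369 and HSP26 from 221 to 4706. The arginine biosynthesis gene ARG1 rose by 2.89, the cell wall sensor WSC4 by 2.69, the signalling protein GPG1 by 2.61 and the weak-acid exporter PDR12 by 1.81 on glucose and 3.18 on xylose. RGI1 and IGD1 rose by 2.29 and 2.23, the mitochondrial protein FMP33 by 2.07 and the stationary-phase gene MOH1 by 2.06. The DNA repair gene MMS22 had an estimate of 2.68 and the pheromone arrest gene FAR3 of 2.29, but MMS22 was at -0.58 through another of its probe sets under a lower floor. Among the genes of this group after the heat shock pair, the limma adjusted p ran from 0.0165 for WSC4 to 0.0355 for MOH1, and each was higher in 2 of 2 pairs.

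FET3, the copper oxidase of high-affinity iron uptake, had the lowest estimate, -3.79 (limma adjusted p = 0.0189, lower in 2 of 2 pairs), going from 1629 to 107 on glucose and from 1896 to 152 on xylose. The arginase CAR1 was at -2.92, the ribosome assembly protein NOP56 at -2.81 and DBP2 at -2.79, with limma adjusted p of 0.0165, 0.0165 and 0.0246 and lower values in 2 of 2 pairs for each. The other 8 of the 12 lowest genes have high-numbered probe sets, in the stretch where the oxygen-limited arrays were dimmer in general. They were the autophagy gene ATG27 at -3.13, the RNA polymerase I subunit RPA34 at -3.09, the mannosyltransferase PMT2 at -3.08, the secretory cargo gene ERP2 at -2.99, the cysteine gene CYS3 at -2.98, the chaperonin CCT3 at -2.90, the replication factor RFA3 at -2.81 and the mitochondrial import gene TIM17 at -2.70. FMP33, among the highest, lies in the same stretch of numbers.

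**Figure D3:**
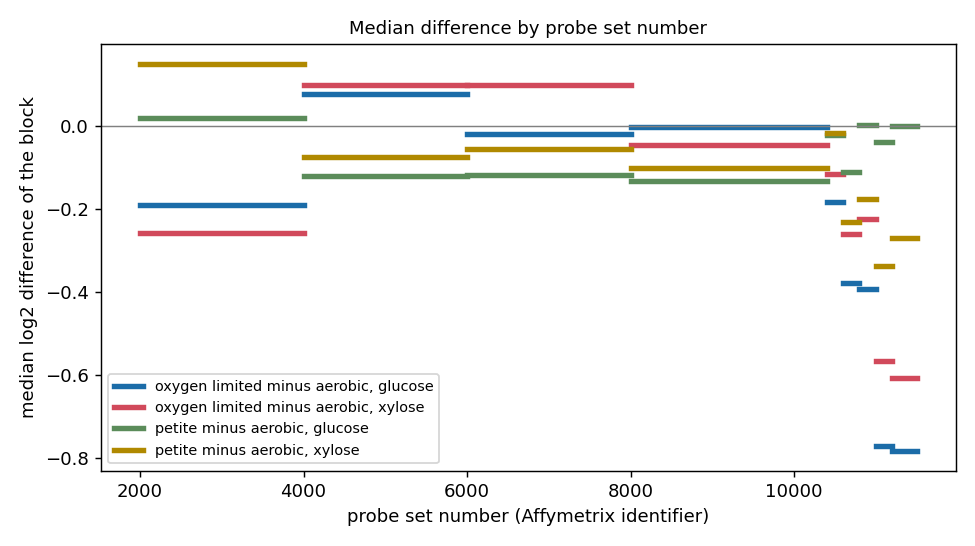
Median log2 difference of blocks of probe sets along the probe set numbers, for oxygen-limited and for petite cells minus aerobic cells on each sugar. Over the whole high-numbered stretch the oxygen-limited medians were -0.47 on glucose and -0.32 on xylose, against -0.02 and 0.00 for all lower numbers, of which those under 4000 were at -0.19 and -0.26.

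Iron uptake genes were among the decreases. Of 18 iron regulon genes, 0 rose, 9 fell and 9 did not pass, with 10 falling when adjusted over the list alone and a median of -1.15, or -0.80 without scaling. After FET3 the largest were the ferric reductase FRE1 at -2.66 (limma adjusted p = 0.0304, lower in 2 of 2 pairs), the cell wall mannoprotein FIT2 at -2.39 (limma adjusted p = 0.0195, lower in 2 of 2 pairs) and the siderophore transporter SIT1 at -2.39 (limma adjusted p = 0.0181, lower in 2 of 2 pairs). Among 40 amino acid biosynthesis genes, 2 rose and 12 fell, also when adjusted over the list alone, with TRP3 at -1.52, LYS4 at -1.33 and MET14 at -1.29 below and ARG1 above. TRP3 and MET14 have high-numbered probe sets. MET16, a sulfate assimilation gene, was the other that rose, by 1.03. Their median in the glucose pair, -0.30, turned to 0.07 without scaling and 0.10 with quantile normalization.

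Some genes of protein synthesis fell. Of 27 ribosome biogenesis genes 24 fell, 25 when adjusted over the list alone, with a median of -1.09, or -0.74 without scaling and -0.97 with quantile normalization; the nuclear export factor NOC2 fell by 2.11. Of 80 cytosolic ribosomal protein genes 34 fell and 0 rose, with 46 falling when adjusted over the list alone, RPL9B at -2.36 and a median of -0.68, or -0.33 without scaling and -0.25 with quantile normalization. Of 67 mitochondrial ribosome genes 18 fell and 1 rose, with 20 and 1 when adjusted over the list alone; MRPS18 was at -2.20 and MRP4 at -2.07 below, and MRP49, with a high-numbered probe set, at 0.67 above. RNA quality and labelling were not separated from these decreases: the 3' to 5' ratio of SPT15 was 2.48 and 3.77 on the oxygen-limited arrays against 1.398 and 0.512 on the aerobic ones, that of ACT1 1.08 and 1.19 against 1.62 and 1.26, and ribosomal RNA probes were at 105 and 99.7 against 51.8 and 43.5. Spike-in controls had geometric means of 159.7 and 158 on the oxygen-limited arrays against 460.2 and 383.

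Respiratory genes moved in both directions. COX5B, the hypoxic form of a cytochrome oxidase subunit, rose by 2.04 (limma adjusted p = 0.0165, higher in 2 of 2 pairs), and CYC7, the hypoxic cytochrome c, by 1.74 (limma adjusted p = 0.0181, higher in 2 of 2 pairs). The aerobic cytochrome c gene CYC1 fell by 1.45 (limma adjusted p = 0.0181, lower in 2 of 2 pairs) and has a high-numbered probe set. The external NADH dehydrogenase NDE2 rose by 1.75 (limma adjusted p = 0.0181, higher in 2 of 2 pairs). NDE2 and CYC1 were the only 2 of 22 respiratory chain genes that passed, COX26 was at 2.01 without passing, and the list median of -0.27 turned to 0.08 without scaling and 0.10 with quantile normalization. The ATP synthase median of -0.21, with 0 rising and 0 falling, turned to 0.14 and 0.26 in the same settings. In the glucose pair the respiratory chain median was -0.80 and in the xylose pair 0.25. TCA cycle genes had a median of -0.58, or -0.22 without scaling and -0.13 with quantile normalization; IDH1 fell by 1.17 and FUM1 by 1.03, with limma adjusted p of 0.0226 and 0.0316 and lower values in 2 of 2 pairs for each. Of 22 hypoxic and anaerobic genes 2 rose, COX5B and CYC7, and 2 fell, also when adjusted over the list alone. Those that fell were ANB1, an anaerobic translation factor, at -1.55, with a high-numbered probe set, and the ribonucleotide reductase inhibitor SML1 at -1.01.

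Some stress and carbohydrate lists held members that rose and members that fell under oxygen limitation, and in others the members that passed over all genes went 1 way. Among 22 heat shock genes 4 rose and 3 fell, with 4 and 4 when adjusted over the list alone; HSP42 rose by 1.37 and SPI1 by 1.77, whereas SSE1 fell by 1.49. Of 17 trehalose and glycogen genes 3 rose, GLG1 (with a high-numbered probe set), ATH1 and GLC3, and 0 when adjusted over the list alone, with a median of 0.45. Among 11 thiamine genes with a median of 0.75, 3 rose, also when adjusted over the list alone, with THI20 at 1.14. The 7 galactose genes had a median of 0.56, with 3 rising in both counts and the activator GAL4 at 0.95. Of 11 pentose phosphate genes with a median of -0.78, or -0.42 without scaling and -0.36 with quantile normalization, 2 rose and 2 fell, with 3 and 5 when adjusted over the list alone; NQM1 rose by 1.93 and the lactonase SOL4 by 1.53, while the ribulose-phosphate epimerase RPE1, whose probe set is high-numbered, fell by 2.22 and RKI1 by 1.15. In hexose transport the sensors SNF3 and RGT2 rose by 1.51 and 1.23 and the transporter HXT2 fell by 2.19. Of 18 oxidative stress genes 5 fell, and 6 fell and 1 rose when adjusted over the list alone; their median of -0.14 turned to 0.21 without scaling. Glycolysis genes had a median of 0.05 and a mean of -0.03, with camera pointing up (adjusted p = 0.605), and 0 passed.

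Limma camera with the preset correlation placed 10 lists away from the other genes. Lower were ribosome biogenesis (adjusted p = 2.2e-09), cytosolic ribosomal proteins (4.0e-09), the mitochondrial ribosome (8.2e-04), the iron regulon (0.00451) and amino acid biosynthesis (0.0329). Higher were the galactose regulon and trehalose and glycogen (both 0.012), thiamine and meiosis genes (both 0.023) and a-specific genes (0.0236). None held in camera with an estimated correlation, where the smallest was adjusted p = 0.93, but that form could hardly call any list here. Estimated correlations lay above the preset 0.01 for all of these lists but the galactose regulon. They were 0.12 for ribosome biogenesis and 0.40 for cytosolic ribosomal proteins, so the preset adjusted p may be too small. In limma fry the smallest adjusted p for a shift in 1 direction was 0.0505. For changes in either direction it was 0.00627, for glycerol, hypoxic and phosphate genes, none of which camera called. Of the lists that camera called, trehalose and glycogen (0.0979) and thiamine (0.069) missed 0.05 in that form of fry, and the others passed. Of 22 ergosterol genes 3 fell, 1 when adjusted over the list alone, with ERG4 at -1.92 and a median of -0.42, or -0.067 without scaling and -0.068 with quantile normalization. Drug resistance at -0.15 turned to 0.12 without scaling while camera pointed up (adjusted p = 0.857).

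In the single pairs, 238 genes were at least 2-fold higher and 609 lower under oxygen limitation on glucose, of 5292, and 497 higher and 815 lower on xylose, of 5307. The spread between probe sets of the same gene was 0.58 on glucose and 0.55 on xylose. Without scaling the balance turned, with 667 higher and 294 lower on glucose and 900 and 479 on xylose; with quantile normalization the counts were 310 and 488, and 593 and 635. The pairs shared 135 higher genes, against 21.6 if independent, and 423 lower genes, against 94.8. Both pairs set oxygen-limited arrays against aerobic ones and share differences in array set, sugar concentration and cell density. The excess therefore does not point to oxygen alone. On glucose ARG1 was higher by 4.09, MMS22 by at least 3.03 but at -0.81 through another of its probe sets under a lower floor, ALA1 by 2.99, SPL2 by 2.95 and WSC4 by at least 2.89. FET3 was lowest at -3.93, with ATG27 at -3.49 or below, NCE103 at -3.32, FRE1 at -3.29 and RFA3 at -3.29 or below. On xylose HSP30 was higher by 5.44, HSP26 by 4.41, FDH1 by at least 4.05, PIR3 by 3.97 and the osmotic stress gene SIP18 by 3.53. FET3 at -3.64, ADH2 at -3.54, CYS3 at -3.46, the cysteine gene CYS4 at -3.19 and the inosine monophosphate dehydrogenase IMD4 at -3.15 were lowest.

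The third comparison asks how the respiration-deficient mutant differs from its aerobic parent over both sugars; sugar concentration and culture volume of the petite cultures are not stated, and the xylose sample, glucose-grown and then kept 24 hours on xylose, has no stated cell density. The mitochondrial gene OLI1 fell and CPP3 rose in the mutant, and no other gene passed in the main setting. Lists of the mitochondrial genome, respiratory chain, ATP synthase and ribosomes had negative medians, and those of hypoxic, hexose transport and fatty acid oxidation genes positive ones. Limma camera called lists with the preset correlation of 0.01, but none with an estimated correlation, where the smallest was adjusted p = 0.686. That second form could hardly call any list with 2 residual degrees of freedom, so it leaves the shifts undecided. Limma called 1 gene higher and 1 lower, with unadjusted counts of 636 higher and 1211 lower at a p under 0.05. At a limma adjusted p under 0.06 the counts were 196 higher and 379 lower, so they hinge on the threshold. They also hinge on the setting: limma called 0 in either direction with quantile normalization (unadjusted 661 and 918), with the floor at the 40th percentile (482 and 1137) and with the mean over probe sets (619 and 1230), but 219 higher and 340 lower with the floor at the 10th percentile and 133 and 230 with a variance trend. Without the oxygen-limited pair it called 0 higher and 1 lower (unadjusted 577 and 1081). As deposited, where the petite arrays lie 0.31 above the aerobic glucose array in their medians, the counts were 168 and 31, or 84.4% higher against 50.0%.

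OLI1, the mitochondrially encoded subunit of ATP synthase, was the gene that fell. Its intensity was 2313 on glucose and 2280 on xylose in aerobic cells and at the floor in both petite samples, an estimate of -5.22 (limma adjusted p = 0.048, lower in 2 of 2 pairs). COX1, the mitochondrial cytochrome oxidase subunit, went from 963 and 1393 to the floor in both petite samples and missed the threshold at -4.23 (limma adjusted p = 0.0515, lower in 2 of 2 pairs). The cytochrome b gene COB and ATP8 were also at the floor in the petite samples, at -1.10 and -0.88, but started from 134 or less; ATP6 was at -0.43. COX3 was at 1.44 in the other direction, with intensities of 137 and 204 in the petite samples, and COX2 and VAR1 were at the floor on every array. Among 6 mitochondrial genes in the fit 1 fell, and 4 fell and 1 rose when adjusted over the list alone, with a median of -0.99.

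CPP3, a protein of poorly known function, was the gene that rose, by 2.65 (limma adjusted p = 0.048, higher in 2 of 2 pairs), and it also rose on xylose by 1.33 (limma adjusted p = 0.0386, higher in 3 of 3 pairs). The next highest genes missed the threshold with limma adjusted p from 0.0515 to 0.0841 and were higher in 2 of 2 pairs each. They included HSP26 at 3.18, the sulfiredoxin SRX1 at 2.95, PIR3 at 2.88, SPG4 at 2.82, the drug transporter relative YHK8 at 2.61, the seripauperin PAU19 at 2.61 and the glutamate dehydrogenase GDH3 at 2.56. MOH1 at 2.20 on glucose and 2.80 on xylose, the aryl-alcohol dehydrogenase AAD4 at 2.49, GPG1 at 2.40 and the peroxisomal catalase CTA1 at 2.37 completed them. GDH3, SRX1 and PIR3 have high-numbered probe sets. Among the lowest that missed, HTB2, a histone H2B gene, was at -3.38, SSA2 at -2.48, the mating-type switching gene HO at -2.39, the copper transporter CTR1 at -2.33 and FRE1 at -2.31. The translation-related SRO9 and the membrane gene INA1 were both at -2.23, with DBP2 at -2.15, NOP56 at -2.13 and the ATP synthase inhibitor INH1 at -2.10; their limma adjusted p ran from 0.0515 to 0.073, lower in 2 of 2 pairs each.

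Respiratory lists had negative medians in the mutant. Of 22 nuclear respiratory chain genes, 0 passed over all genes, and 19 fell and 1 rose when adjusted over the list alone, with a median of -1.37. COX6 was at -1.89, COX4 at -1.82 and COX5A at -1.74, whereas NDE2 went against the list at 1.37. Of 14 ATP synthase genes with a median of -1.25, 12 fell when adjusted over the list alone, led by ATP3 at -2.09 and ATP1 at -1.87. Of 16 TCA cycle genes with a median of -0.89, 5 fell when adjusted over the list alone, with MDH1 at -1.57 and LPD1 at -1.42. The 12 genes of the retrograde response, through which mitochondrial loss is signalled to the nucleus, had a median of -0.33. In either count 0 passed, with CIT2 at -0.65 and DLD3 at -1.68. For 4 histone genes the median was -1.11 and 3 fell when adjusted over the list alone. Without scaling the medians were -1.09 for the respiratory chain, -0.97 for ATP synthase, -0.61 for the TCA cycle and -0.045 for the retrograde response.

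Other lists had medians of either sign. Of 22 hypoxic genes with a median of 0.47, 6 rose when adjusted over the list alone, with COX5B at 1.32 and the seripauperin PAU7 at 1.04; OLE1, the fatty acid desaturase, went against the list at -1.24. The 12 hexose transport genes had a median of 0.47, with HXT5 at 2.32, and 19 fatty acid oxidation genes a median of 0.48, with POT1 at 1.72; 1 rose in each when adjusted over the list alone. Ribosome biogenesis genes had a median of -0.68, 20 falling when adjusted over the list alone, and cytosolic ribosomal proteins -0.58, with 29 falling; without scaling these medians were -0.40 and -0.30. RNA quality and labelling were not separated from the petite differences: ACT1 had a 3' to 5' ratio of 2.15 and 1.84 on the petite arrays against 1.62 and 1.26 on the aerobic ones, and SPT15 2.27 and 2.104 against 1.398 and 0.512. Spike-in controls had geometric means of 813 and 775 on the petite arrays against 460.2 and 383. In drug resistance the median was -0.20 and the mean 0.03, with camera pointing up (adjusted p = 0.789), the transporters PDR10 at 2.09 and PDR15 at 1.85, the lipid transfer protein PDR16 at -1.48, and 4 rising and 2 falling when adjusted over the list alone. Medians of ethanol, glycerol and iron genes at -0.27, -0.28 and -0.22 turned to 0.01, 0.00 and 0.06 without scaling.

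Limma camera with the preset correlation placed 14 lists away from the other genes in the mutant. The adjusted p was 2.5e-07 for both cytosolic ribosomal proteins and ribosome biogenesis, 8.8e-06 for the respiratory chain, 3.5e-05 for ATP synthase, 0.00467 for the TCA cycle, 0.00729 for ergosterol, 0.02 for the mitochondrial ribosome and 0.0443 for the mitochondrial genome, all lower. Higher lists were hypoxic and fatty acid oxidation genes (both 0.00205), hexose transport (0.00729), thiamine (0.00748), meiosis (0.0107) and galactose genes (0.0389). None held in camera with an estimated correlation, where the smallest was adjusted p = 0.686, but that form could hardly call any list here. Estimated correlations lay above the preset 0.01 for all of these lists but the galactose genes. They were 0.82 for the respiratory chain and 0.90 for ATP synthase, so the preset adjusted p may be too small. In limma fry the smallest adjusted p for a shift in 1 direction was 0.129. For changes in either direction it was 0.0334, for ribosome biogenesis, the mitochondrial ribosome and hypoxic genes. Glycolysis, ethanol and drug resistance genes, which camera did not call, had the same value. Of the other lists that camera called, only the mitochondrial genome (0.0337) passed in that form of fry.

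In the single pairs, 249 genes were at least 2-fold higher and 266 lower in the petite mutant on glucose, of 5272, and 446 higher and 712 lower on xylose, of 5287. The spread between probe sets of the same gene was 0.49 on glucose and 0.41 on xylose. Without scaling the balance turned, with 471 higher and 105 lower on glucose and 654 and 417 on xylose; with quantile normalization the counts were 259 and 184, and 467 and 559. The pairs shared 125 higher genes, against 20.6 if independent, and 169 lower genes, against 36.3. Both pairs set petite arrays against aerobic ones and share any difference between those array sets. The excess therefore does not point to the mutation alone. On glucose HSP26 was higher by at least 3.79, the DNA damage gene HUG1 by 3.34, the glyceraldehyde phosphate dehydrogenase TDH1 by 3.29, ADH2 by 3.23 and ALA1 by 3.17. OLI1 at -5.23 or below and COX1 at -3.96 or below were lowest, with PHO84 at -3.33, HTB2 at -3.30 and NCE103 at -3.25. On xylose PIR3 was higher by 4.40, SPG4 by 4.09, YHK8 by at least 3.79, CTA1 by 3.78 and the aquaglyceroporin AQY3 by 3.53. OLI1 at -5.21 or below, COX1 at -4.50 or below, SSA2 at -3.88, HTB2 at -3.45 and the mitochondrial succinate carrier SFC1 at -3.26 or below were lowest.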

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

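Of the tests in this part, those on copies of chromosomes I and X, on probe sets of the same gene, on array sets and on mating type were chosen after the result was seen, the last being put on a-specific genes after STE3 and SAG1 had been tried, while those on list members outside the high-numbered stretch, on MF(ALPHA)2 with the trend removed and on other splits were written before. Standard errors of sets of genes or probe sets are the standard deviation over members divided by the root of their number. Those of differences of medians, 0.36 and 0.25, came from resampling genes, and those of single genes from limma. Members of a set were read on the same arrays and can move together. Their standard errors describe spread over members, not variation between cultures.

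Oxygen-limited arrays were dimmer than aerobic arrays for high-numbered probe sets, a stretch holding 712 of 5462 genes in the fit, with medians of -0.47 on glucose and -0.32 on xylose against -0.02 and 0.00 for all lower numbers, of which those under 4000 were also dim, at -0.19 and -0.26. A trend along the probe set numbers stays open: in 23 genes with probe sets on both sides the median difference was -0.14 (standard error 0.20), and a form of the test chosen after that value was seen gave -0.52 (standard error 0.36, permutation p = 0.0253), which rested on 0.46 in 90 genes used as controls more than on -0.057 in 19 high-numbered ones. Fewer copies of chromosomes I and X did not account for their part of it, since their 48 probe sets with lower numbers had a median of 0.21 (standard error 0.0978), but chromosome XI was not tested and its lower-numbered probe sets were at -0.43 and -0.48, against -0.37 and -0.30 in the stretch. Whether oxygen limitation acted on the genes themselves could not be told from 0.33 (standard error 0.25) in 19 genes. Of the genes that fell under oxygen limitation 23.8% had such probe sets, against 13.0% of all genes in the fit, and 3.64% of those that rose. The stretch stood apart in other pairs too. For xylose minus glucose its median was 0.24 against -0.09 for lower numbers under oxygen limitation, 0.09 against -0.03 in aerobic culture and -0.07 against 0.01 in the petite mutant. For petite minus aerobic cells it was -0.23 against -0.04 on xylose and -0.05 against -0.10 on glucose.

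Ribosome biogenesis genes were lower in the oxygen-limited arrays. The trend along the probe set numbers did not account for this, as the 24 members with lower numbers had a median of -1.06 (standard error over members 0.13) and 21 of them fell. Each oxygen supply was measured in its own pair of arrays, and over 9 spike-in probe sets the smallest distance between an oxygen-limited and an aerobic array was 1.59, against at most 0.279 within a pair, so an effect of the array set could not be told from one of oxygen, sugar concentration or cell density.

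MF(ALPHA)2 was lower on xylose in all 3 backgrounds, with an estimate of -2.95. Cells of the other mating type in the xylose cultures did not account for the whole of it: most cells would have to be of mating type a, yet the 6 genes specific to that type had a median of -0.038 (standard error 0.13), and STE3, which alpha cells alone express, was at -0.16 (standard error 0.17). A smaller share of such cells stays open, since some a-specific genes lay near the floor and other alpha-specific genes differed by pair: in aerobic, oxygen-limited and petite cells MF(ALPHA)1 was at -0.58, 0.05 and -3.69 and SAG1 at -0.68, -1.55 and -1.06. The trend along the probe set numbers did not account for the difference, which was -2.91 (standard error 0.28) with the trend removed. That removal could change little. Probe sets numbered 4000 to 6000, where that of MF(ALPHA)2 lies, had medians on xylose of -0.02, -0.06 and 0.00 in aerobic, oxygen-limited and petite cells. A response to xylose was not tested apart from these and stays open.

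Among the 10 splits of the 6 arrays into 3 and 3, the real split by sugar called 41 genes and the highest other called 0. Only 4 of the 10, the real one among them, separate the arrays of every pair, and the others separate those of 1 pair. With 1 of 10 splits, or 1 of these 4, reaching that count, there were too few splits for a share under 0.05. In the other splits any sugar difference also adds to the residual spread, which lowers their calls. The contrast of 41 with 0 therefore does not measure how far the calls exceed chance.

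Several genes differed in opposite directions between backgrounds or sugars, and these differences were not tested. For xylose against glucose, ACO1 was at 1.37 under oxygen limitation and -1.98 in the petite mutant. FRE1 was at 1.27 and -1.11 in the same pairs. PHO84 was at -2.74 and 3.77 there, and SPL2 at -2.79 and 3.05. NCE103 was at -1.47 in aerobic culture and 3.56 in the petite mutant. RLP7 was at -2.30, -1.28 and 1.37 in aerobic, oxygen-limited and petite cells, and TDH1 at 1.76, 1.56 and -1.15. For oxygen limitation against aerobic culture, ALA1 was at 2.99 on glucose and -1.24 on xylose, and CYB2 at 1.36 and -1.79. For the petite mutant against aerobic culture, ALA1 was at 3.17 on glucose and -1.22 on xylose, HXT1 at -1.18 and 1.72, NCE103 at -3.25 and 1.78, and RLP7 at -1.73 and 1.94.

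List medians also differed in sign, again not tested. On xylose, pentose phosphate genes were at 0.32 in aerobic culture and -0.49 in the petite mutant, and phosphate regulon genes at -0.94 under oxygen limitation and 0.56 in the petite mutant. Both involve the petite pair, where sugar cannot be told apart from growth state. Under oxygen limitation the respiratory chain was at -0.80 on glucose and 0.25 on xylose, and glycolysis at -0.088 and 0.32, where the first turned to 0.29 without scaling and 0.35 with quantile normalization. Of 2770 probe sets without a single gene, 1969 lay above the floor; 7 were at least 2-fold higher on xylose in every background.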

How the results depend on the processing

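The alternatives that dealt with the probe set number trend were chosen after seeing the data, and the others before. With a 3-fold threshold in place of 2-fold, counts higher and lower on xylose were 75 and 13 in aerobic culture (161 and 108 at 2-fold), 184 and 50 under oxygen limitation (457 and 221), and 99 and 47 in the petite mutant (302 and 277). For oxygen limitation they were 34 and 173 on glucose (238 and 609) and 134 and 277 on xylose (497 and 815), and for the petite mutant 72 and 45 on glucose (249 and 266) and 155 and 172 on xylose (446 and 712), since a higher threshold passes fewer genes. The counts that limma gave were 37 higher and 4 lower on xylose, 439 and 868 under oxygen limitation, and 1 and 1 in the petite mutant. With a variance trend, limma called 133 higher and 230 lower in the petite mutant and 7 lower on xylose. With the floor at the 10th percentile, limma called 83 higher and 15 lower on xylose and 219 and 340 in the petite mutant, and 368 genes were at least 2-fold higher under oxygen limitation on glucose. With this floor MMS22 turned from 3.03 to -0.81 on glucose and from 2.68 to -0.58 in the fit, since another probe set was chosen. With the floor at the 40th percentile, limma called 0 genes in either direction on xylose (552 and 419 at an unadjusted p under 0.05) and 0 in the petite mutant (482 and 1137), and 214 were higher under oxygen limitation. On that floor 141 genes were at least 2-fold higher under oxygen limitation on glucose, 150 higher in the petite mutant on glucose and 64 lower on xylose in aerobic culture, and 19 of 42 named genes were still called. With the mean over probe sets, limma called 22 higher and 2 lower on xylose and 0 in either direction in the petite mutant. With quantile normalization, limma called 20 higher on xylose, 558 lower under oxygen limitation and 0 in either direction in the petite mutant. There camera called 6 lists under oxygen limitation (10 otherwise), and the glycolysis median on glucose turned from -0.088 to 0.35. With the values as deposited, the glycolysis median turned to 0.29 and that of cytosolic ribosomal proteins on xylose in aerobic culture from -0.04 to 0.0077. As deposited, limma called 1032 higher and 430 lower under oxygen limitation and 168 and 31 in the petite mutant. As deposited, at least 2-fold differences were 667 higher and 294 lower under oxygen limitation on glucose, 900 and 479 on xylose, 471 and 105 in the petite mutant on glucose and 417 lower on xylose, since scaling moves every gene alike. With the probe set number trend removed, limma called 104 higher and 102 lower in the petite mutant, and without the high-numbered probe sets 130 and 236, with 10 lower on xylose. Without the aerobic pair limma called 42 higher and 7 lower on xylose. Without the oxygen-limited pair it called 0 genes in either direction on xylose and 0 higher in the petite mutant, with 1 of 18 named genes still called, and without the petite pair 12 higher and 0 lower on xylose. For the other changes the cause was not tested.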
